A study of Danio rerio with 6 samples.

How the data were processed

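RNA from fluorescence-sorted zebrafish hepatocytes was measured by RNA sequencing in 6 samples, 3 in the group CTL and 3 in the group lcat OE, with groups and replicate numbers taken from the sample titles. Per the labels' protocols, poly(A) RNA was selected with oligo(dT) beads, fragmented, reverse transcribed with random primers, amplified by PCR and sequenced as circularised libraries. The labels state no strand-specific step, so reads of overlapping antisense genes cannot be told apart, and near-identical paralogs may share reads.

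The authors deposited 1 table of 23745 genes with several units per library. The submitters' processing notes name HISAT, Bowtie2 2.3.4.3, RSEM 1.3.1 and DESeq2 1.4.5 and the build GRCz11, without saying which tool did which step; the annotation and any filter are not given in the sources used here. The read count columns deposited by the authors hold expected counts: 10.8% to 11.8% of genes per library had a count that was not a whole number (tolerance 0). The authors also deposited TPM and FPKM values per library, which are scaled by transcript length and sequencing depth. A further set of deposited columns is a signal made of the counts divided by 1 factor per library, and these columns and the deposited group averages were not used in tests. In the table, 15 gene symbols had the form of dates and were restored from the NCBI gene number. Of the gene numbers, 22127 were found in a RefSeq gene table of assembly GRCz12tu, which was used for names and for which genes neighbour each other; no coordinates were taken from it.

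Expected counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr, TMM factors, robust quasi-likelihood F test, group as the only term), with Benjamini-Hochberg adjustment over the 14096 genes tested and a threshold of 0.05. The tests were two-sided. Standard errors were taken as the absolute log2 fold change divided by the square root of F. CPM values use TMM-scaled library sizes. Where a group had no count, the fold is a bound against a floor of 3 counts per library; where it had 1 to 3 counts, the ratio is given with an exact 95% interval. PCR reads without molecular identifiers are not independent molecules, so these intervals and floors cover counting error only. Total counts were 23695610, 23336591 and 23375499 in CTL 1 to 3 and 23431234, 24890856 and 24657609 in lcat OE 1 to 3. No 2 replicates were alike within sampling noise: chi-square per degree of freedom was 11.6 to 37.3 for pairs within a group.

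Before the data were examined, 39 gene lists and the rule for named genes were fixed. Of 1347 names, 1175 were matched by symbol and 71 by a RefSeq name, and 83 had no match, among them all members of the list of mitochondrially encoded genes, which was not tested. The other 38 lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, with an estimated correlation beside it, adjusted over the lists. With the preset correlation 15 lists passed and with an estimated correlation 0 passed, 2 lists having an unadjusted p under 0.05. The test called fry, which asks whether the genes of a list move on balance 1 way and does not compare them with other genes, called 17 lists.

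Other genes named in the text are said to have been chosen after their values were seen. The named genes are lcat and fabp10a; the 8 largest and 8 smallest log2 fold changes among genes past the threshold with at least 10 CPM in the higher group, no overlap between the groups and a symbol that is not a clone or locus name; and from each list up to 3 (lipid lists) or 2 (other lists) genes past the threshold with the smallest p. Some of the last kind are left out of the text.

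The gene and list tests were tested on simulated data drawn from the means and library sizes of these samples. For lcat OE against CTL over 14114 genes, edgeR recovered 10.4% of genes changed 1.5-fold, 59.7% of those changed 2-fold and 84.8% of those changed 4-fold, and 8 of 111 calls (7.2%) were false. A list shifted by 0.5 on the log2 scale was called by camera with either correlation and by fry, and 0 of the other lists were called. The simulated genes were drawn independently of each other, with a spread set by a formula and not taken from the samples. The simulation therefore does not show how the list tests behave where the genes of a list move together. Alternatives tried were other scaling factors, filters, a replicate block, a fit that is not robust, scaling without the 20 most abundant genes, limma on log2(TPM + 1), log2(TPM + 0.1) and log2(FPKM + 1), DESeq2 1.42.0, leaving out each library, a 2-fold threshold, and other list tests. Chosen after seeing the data were a comparison of 2 against 2 libraries, without CTL 1 and lcat OE 3, and offsets for transcript length. Transcript lengths were not given, so the planned length correction was replaced by one on the length implied by the ratio of deposited counts to TPM, which all 14096 genes have.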

Results

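Hepatocytes were sorted by fluorescence from zebrafish larvae at 6 days post fertilisation, and the poly(A) RNA of 2000 sorted cells per sample was sequenced. The 3 CTL libraries came from larvae that carry a green reporter under the promoter of fabp10a, a liver fatty acid binding protein gene used to mark hepatocytes. The 3 lcat OE libraries came from larvae that carry this reporter and a second transgene in which the same promoter drives lcat together with a red reporter. The gene lcat encodes lecithin-cholesterol acyltransferase, a liver-secreted enzyme that esterifies cholesterol on lipoproteins. The design has 1 comparison, lcat OE against CTL, and its stated purpose is to find transcript changes that go with early fat accumulation in the liver when lcat is overexpressed. Neither group carries the red reporter without lcat. Effects of lcat therefore cannot be told apart from those of the red reporter or of other differences between the fish lines. The libraries held 23336591 to 24890856 counts, of which 41.41% to 45.23% fell on the 20 most abundant genes. The labels do not say whether the replicates came from separate clutches or separate sorts, so the p-values measure the spread between these samples, which may be technical.

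The overexpressed gene was higher in all 3 lcat OE libraries. In CTL, lcat (NCBI gene 793137) had counts-per-million (CPM) values of 148.7, 119.9 and 144.1, and in lcat OE of 3255, 2610 and 1958. The group means were 138 ± 15.5 CPM and 2608 ± 648 CPM (SD, n = 3 each), a log2 fold change of 4.24 (SE 0.20, adjusted p = 1.35e-06), or 18.96-fold. Reads of the transgene and of the endogenous gene are not told apart here. The gene whose promoter drives both transgenes, fabp10a (NCBI gene 171481), had 8990.3 ± 527 CPM in CTL and 9853 ± 1103 CPM in lcat OE, a log2 fold change of 0.13 (SE 0.12, adjusted p = 0.427). The fabp10a log2 fold change turned to -0.03 on deposited TPM with either pseudocount, and to -0.21 (adjusted p = 0.1) with offsets for transcript length, an alternative chosen after seeing the data; its adjusted p lay between 0.1 and 0.754 over all alternatives.

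**Figure D1:**
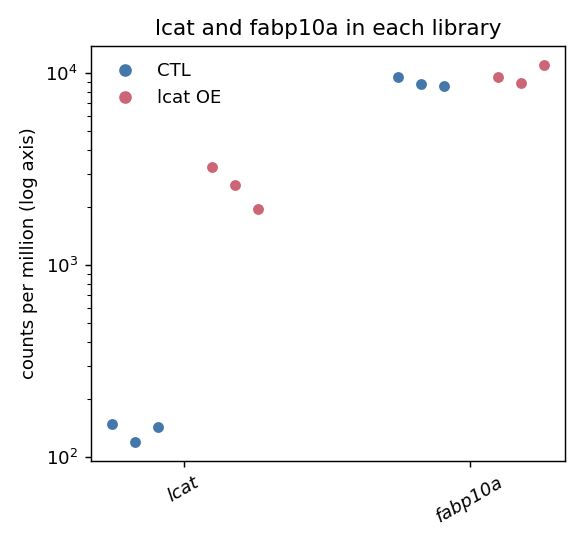
CPM (log axis) of lcat and fabp10a in each of the 6 libraries, with 1 point per library. The 3 lcat OE libraries had 1958 to 3255 CPM of lcat against 119.9 to 148.7 CPM in CTL, while the fabp10a values of the 2 groups overlapped.

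Expression differed widely between the groups. Of 14096 genes tested, 2293 were higher and 2303 lower in lcat OE. A change of 2-fold or more was seen in 1075 of the higher and 1264 of the lower genes, and one of 8-fold or more in 357 and 193. The largest named rises were in mllt11 (0.438 to 171 CPM, log2 fold change 8.58, SE 0.28), ponzr3 (7.91, SE 0.77), slc14a2, a urea transporter gene (7.52, SE 0.46), ponzr4 (7.32, SE 0.65), rhcgl1, an ammonium transporter gene of the Rh family (7.01, SE 0.41), fut9d (6.78, SE 0.25), the keratin gene krt17 (6.4, SE 0.62) and aep1 (6.2, SE 0.36). The slc14a2 value rests on 4 counts in CTL and was 8.73 without CTL 3. The values of the 3 CTL and 3 lcat OE libraries did not overlap for 6724 genes, 47.7% of those tested, where chance gives 10%. The first principal component held 73.6% of the variance and separated the groups.

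The split of the calls differed between settings. Of the called genes, 49.9% were higher in lcat OE with TMM factors and 38.8% with library totals, where only the scaling differs. With limma, where the unit, the pseudocount and the test differ too, 39.8% were higher on log2(FPKM + 1), 30.2% on log2(TPM + 1) and 30.8% on log2(TPM + 0.1). Library totals moved the median log2 fold change of all genes from -0.02 to -0.11, and log2(TPM + 0.1) moved it to -0.18.

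The largest named falls included genes known from pigment cells, photoreceptors and muscle, and an immediate early gene. The pigment gene gch2, a GTP cyclohydrolase of the pteridine pathway, fell from 153 ± 100.1 to 0.157 ± 0.03 CPM (SD, n = 3 each; log2 fold change -9.89, SE 0.83), and without CTL 2 the change was -9.23. No aox5 read was counted in lcat OE, so aox5 was at least 140.3-fold lower, against a floor of 3 counts per library. The aox5 adjusted p was 0.0432 with all libraries, 0.122 without CTL 3, 0.0937 without lcat OE 1, 0.0704 without lcat OE 2 and 0.0863 without lcat OE 3. It passed with 12 of 20 alternatives (3.11e-11 to 0.122). With 1 count in lcat OE, slc22a7a had a CTL to lcat OE ratio of 2830 (95% counting interval 507 to 112000) and bscl2l a ratio of 1330 (238 to 52400). Without CTL 2 aox5 was at least 77.8-fold lower, and the ratios were 1720 (308 to 68000) for slc22a7a and 681 (122 to 27000) for bscl2l. The slc22a7a ratio was 1850 (332 to 73200) without lcat OE 1 and 1830 (328 to 72200) without lcat OE 2. That of bscl2l was 870 (156 to 34400) without lcat OE 1. With no count left, slc22a7a was at least 325-fold lower without lcat OE 3 and bscl2l at least 141-fold lower without lcat OE 2. The slc22a7a adjusted p was 0.0548 without lcat OE 3 (4.93e-18 to 0.0892 over the alternatives), and that of bscl2l was 0.0752 without lcat OE 2 (2.91e-10 to 0.0752). These intervals cover counting error only, and the CTL libraries differed among themselves, with 77.9, 267 and 114 CPM of gch2. The log2 fold change was -4.25 (SE 0.34) for the cone opsin gene opn1sw1, -4.3 (SE 0.52) for the muscle actin gene acta1a, -4.39 (SE 0.46) for the early response gene egr2b and -3.98 (SE 0.58) for rpain.

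Markers of cell types other than hepatocytes differed in opposite directions. Epidermal genes were higher in lcat OE: cyt1l went from 53.5 ± 16.9 to 3321 ± 614 CPM (SD, n = 3 each; log2 fold change 5.96, SE 0.31) and cyt1 from 93.8 ± 34.7 to 3353 ± 620.3 CPM (5.16, SE 0.35). Of 20 epidermal markers 15 rose and 1 fell (15 and 2 adjusted over the list alone), with a median of 3.25 (adjusted p = 1.15e-07; adjusted p = 0.585 with an estimated correlation). Of 11 macrophage markers 7 rose and 1 fell (9 and 1 adjusted over the list alone; median 1.34, adjusted p = 0.00368; adjusted p = 0.585 with an estimated correlation), with ctss2.2 at 1.2 (SE 0.20) and ctss2.1 at 5.4 (SE 0.83), the latter 4.73 without lcat OE 3. The macrophage median was 2.08 with no filter on low counts, 0.43 on log2(TPM + 1) and 0.52 on log2(FPKM + 1). These macrophage genes held 0.00251% of counts in CTL and 0.00443% in lcat OE. Of 24 matched macrophage genes the filter on low counts kept 11, with 3 at 1 CPM or more in CTL and 7 in lcat OE. Some may thus have been tested only because they are high in lcat OE. The most abundant was grn1 (15.5 and 26.5 CPM), named after its values were seen.

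Pancreas, muscle, neural, fibroblast and endothelial markers were lower in lcat OE as lists. Of 23 exocrine pancreas markers 0 rose and 9 fell (0 and 11 adjusted over the list alone; median -2.76, adjusted p = 3.05e-06; adjusted p = 0.585 with an estimated correlation), and their share of counts was 0.138% in CTL and 0.0218% in lcat OE. The pancreas median was -3.47 without lcat OE 3. The lipase gene cel.2 fell from 6.72 to 0.916 CPM (-2.90, SE 0.57); it was at -3.63 without lcat OE 3, and its adjusted p was 0.0552 without lcat OE 1. Of 19 skeletal muscle markers 0 rose and 8 fell (0 and 11 adjusted over the list alone; median -2.67, adjusted p = 7.01e-05; adjusted p = 0.585 with an estimated correlation), and the median was -1.50 without CTL 3, -1.05 on log2(TPM + 1) and -1.11 on log2(FPKM + 1). The fry test missed the pancreas (adjusted p = 0.0579), muscle (0.0768) and stellate cell (0.0583) lists. Of 20 neural markers 1 rose and 11 fell (1 and 12 adjusted over the list alone; median -1.34, adjusted p = 7.01e-05; adjusted p = 0.585 with an estimated correlation), with the rod opsin gene rho at 26.6 CPM in CTL and 2.14 CPM in lcat OE. The neural median was -0.26 on log2(TPM + 1) and -0.28 on log2(FPKM + 1). Of 16 stellate cell and fibroblast markers 0 rose and 5 fell (0 and 6 adjusted over the list alone; median -0.56, adjusted p = 0.00342; adjusted p = 0.585 with an estimated correlation), with the collagen gene col6a1 at -3.21 (SE 0.21); this call was lost with at least 5 CPM in 3 libraries (0.0688, the highest of 19 alternatives, from 4.28e-05). The stellate median was -1.38 with no filter on low counts, -0.90 with 2 against 2 libraries, -0.29 on log2(TPM + 1) and -0.26 on log2(FPKM + 1). Of 12 endothelial markers 2 rose and 5 fell (2 and 7 adjusted over the list alone; median -1.69, adjusted p = 0.0364; adjusted p = 0.585 with an estimated correlation). Their share of counts went from 0.00153% to 0.00205%, and the most abundant member sox7, named after its values were seen, rose from 2.43 to 13.3 CPM. The endothelial adjusted p was 0.0516 without CTL 2, 0.0585 without CTL 3, 0.0764 with library totals and up to 0.301 on deposited TPM or FPKM, where the median was -0.28 on log2(TPM + 1) and log2(FPKM + 1) and -0.88 on log2(TPM + 0.1). The lowest endothelial adjusted p of 18 alternatives was 0.000147. The gene cldn5b, with 75 counts in CTL and 2 in lcat OE, had a ratio of 36.4 (9.74 to 306), or 23.9 (6.39 to 201) without lcat OE 1.

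Hepatocyte markers did not pass as a list. Their share of counts was 22.6% in CTL and 26.8% in lcat OE. Of 29 genes 3 rose and 2 fell, with equal counts adjusted over the list alone (median 0.13, adjusted p = 0.485; -0.04 and -0.05 on log2(TPM + 1) and log2(TPM + 0.1)), among them the transferrin gene tfa (21124 to 33597 CPM, 0.67, SE 0.11) and apom (0.87, SE 0.17), both higher; the apom adjusted p was 0.117 with 2 against 2 libraries (2.33e-05 to 0.117 over 20 alternatives). Of 16 biliary markers 2 rose and 6 fell, with equal counts adjusted over the list alone (adjusted p = 0.109; 0.274% of counts in CTL and 0.496% in lcat OE, but 0.253% and 0.147% without krt4, which is also an epidermal marker and was named after its values were seen), with the keratin genes krt8 at -1.24 (SE 0.14) and krt18 at -1.23 (SE 0.15). Neutrophil markers had 1 of 6 higher and 2 lower, with equal counts adjusted over the list alone (adjusted p = 0.0919; adjusted p = 0.011 by fry), with abcb9 at -1.42 (SE 0.23). Erythroid markers had 2 of 11 higher and 0 lower by edgeR, and 0 of either adjusted over the list alone, while the list median was below 0 (-0.65, adjusted p = 0.545). Intestinal markers had 2 of 10 higher and 1 lower, with equal counts adjusted over the list alone (adjusted p = 0.50; adjusted p = 0.0283 by fry); they include apoa4b.2 and fabp2 (0.80, SE 0.15), and the median (0.17) and mean (-0.06) differed in sign. The intestinal median turned to -0.32 with no filter on low counts and was under 0 on deposited TPM.

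**Figure D2:**
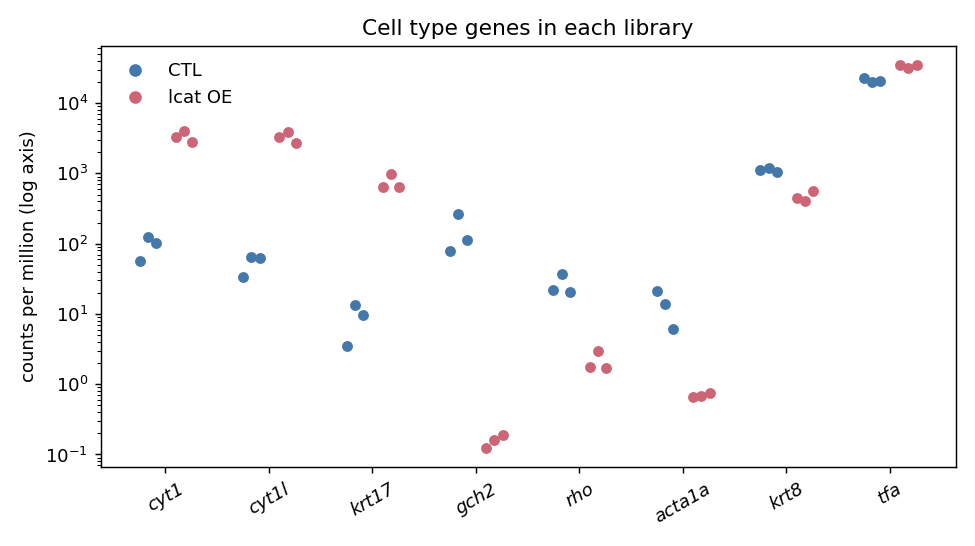
CPM (log axis) of 8 genes of different cell types in each of the 6 libraries, with 1 point per library. The epidermal genes cyt1, cyt1l and krt17 were higher in all 3 lcat OE libraries, and gch2, rho and acta1a were lower in all 3.

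Lipid genes moved in both directions. Of the 12 lipid lists, 2 were higher and 1 was lower by camera with the preset correlation, and each of these 3 had an adjusted p = 0.585 with an estimated correlation. Some fatty acid elongase genes rose: elovl7a went from 0.600 to 13.4 CPM (log2 fold change 4.47, SE 0.32), elovl6l from 0.835 to 10.7 CPM (3.66, SE 0.30) and elovl1a from 2.60 to 19.3 CPM (2.89, SE 0.26). In the list of fatty acid synthesis and desaturation, 8 of 20 tested genes rose and 2 fell, with the same 8 and 2 adjusted over the list alone, and the median log2 fold change was 0.70 (adjusted p = 0.0364; adjusted p = 0.585 with an estimated correlation). The first of these was 0.0671 without CTL 3 and 0.0988 without lcat OE 1, where the median was 0.23; over 19 other scalings, filters, units and left-out libraries it lay between 0.00878 and 0.0988. The median of the synthesis list was 0.42 on log2(TPM + 1) and 1.06 with 2 against 2 libraries. The more abundant members fads2, elovl2 and fasn, named after their values were seen, did not pass: fads2 had 111 CPM in CTL and 183 CPM in lcat OE (adjusted p = 0.343), elovl2 had 92.9 and 165 CPM (0.369) and fasn 10.7 and 9.76 CPM (0.608). The desaturase gene scd, also named after its values were seen, fell from 2.36 to 0.234 CPM (adjusted p = 0.000335). The epidermal markers, which rose in the same libraries, held 0.0635% of counts in CTL and 1.31% in lcat OE. Whether the elongase rises lie in hepatocytes or in epidermal cells was not tested.

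Genes of fatty acid oxidation in mitochondria were higher as a list. In this list 12 of 24 genes rose and 1 fell (15 and 1 adjusted over the list alone), with a median log2 fold change of 0.34 (adjusted p = 0.00368; adjusted p = 0.585 with an estimated correlation). The median was 0.14 on log2(TPM + 1) and 0.15 on log2(TPM + 0.1). In the same libraries the epidermal markers went from 0.0635% to 1.31% of counts, and a link to the oxidation list was not tested. The isomerase gene eci1 rose from 56.3 to 100.7 CPM (log2 fold change 0.84, SE 0.11) and the reductase gene decr1 from 79.3 to 134 CPM (0.76, SE 0.12). The member that fell was mlycd, which encodes malonyl-CoA decarboxylase (22.0 to 5.91 CPM, log2 fold change -1.89, SE 0.18). In the list of ketone body metabolism, 3 of 7 genes rose and 0 fell, with equal counts adjusted over the list alone, and the list missed the threshold (adjusted p = 0.109) but passed without lcat OE 1 (0.0467, the lowest of 19 alternatives, up to 0.209) and by fry (0.0222). Among those that rose were bdh2, by a log2 fold change of 0.53, and oxct1b, by 0.37. The oxct1b adjusted p was 0.119 without CTL 2, 0.0994 without CTL 3 and 0.0541 without lcat OE 2 (0.00794 to 0.119 over 20 alternatives). Of 36 peroxisomal genes 10 rose and 5 fell (11 and 5 adjusted over the list alone; list adjusted p = 0.257), among them scp2b (0.84, SE 0.11) and pecr (0.58, SE 0.11), which were higher, and decr2 (-0.72, SE 0.14), which was lower.

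Among the lipid droplet and lipolysis genes that passed the test, more fell than rose. The droplet coat gene plin2 fell from 80.4 ± 17.8 to 5.53 ± 2.0 CPM (SD, n = 3 each; log2 fold change -3.86, SE 0.30, adjusted p = 0.000138). In the list of triglyceride synthesis and lipid droplets, 3 of 28 genes rose and 7 fell, with equal counts adjusted over the list alone, and the list did not pass (median log2 fold change -0.23, adjusted p = 0.141; adjusted p = 0.0128 by fry). The acyltransferase gene agpat2 fell (-0.86, SE 0.13), while agpat9l rose from 0.178 to 1.37 CPM. Among the members that fell were bscl2l and zgc:162150, the latter matched through its RefSeq name plin6. Both are also on a list of xanthophore (yellow pigment cell) genes chosen after the results were seen. The bscl2l ratio of CTL to lcat OE was 1330 (95% counting interval 238 to 52400). With no count in lcat OE, zgc:162150 was at least 211.3-fold lower. Whether these falls lie in hepatocytes or in pigment cells was not tested. In the lipolysis list 1 of 21 genes rose and 9 fell (1 and 10 adjusted over the list alone), with a list adjusted p = 0.0761. The lipolysis list passed without lcat OE 3 (adjusted p = 0.0257), on log2(TPM + 1) (0.02) and on log2(FPKM + 1) (0.0249), within 0.02 to 0.209 over 19 alternatives. Among the genes that fell were lipeb, a hormone-sensitive lipase gene (-0.96, SE 0.20), pnpla6 (-0.81, SE 0.17) and g0s2, whose product inhibits a triglyceride lipase (-0.88, SE 0.17). Another was cel.2 (-2.90, SE 0.57), which is also on the list of exocrine pancreas markers.

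**Figure D3:**
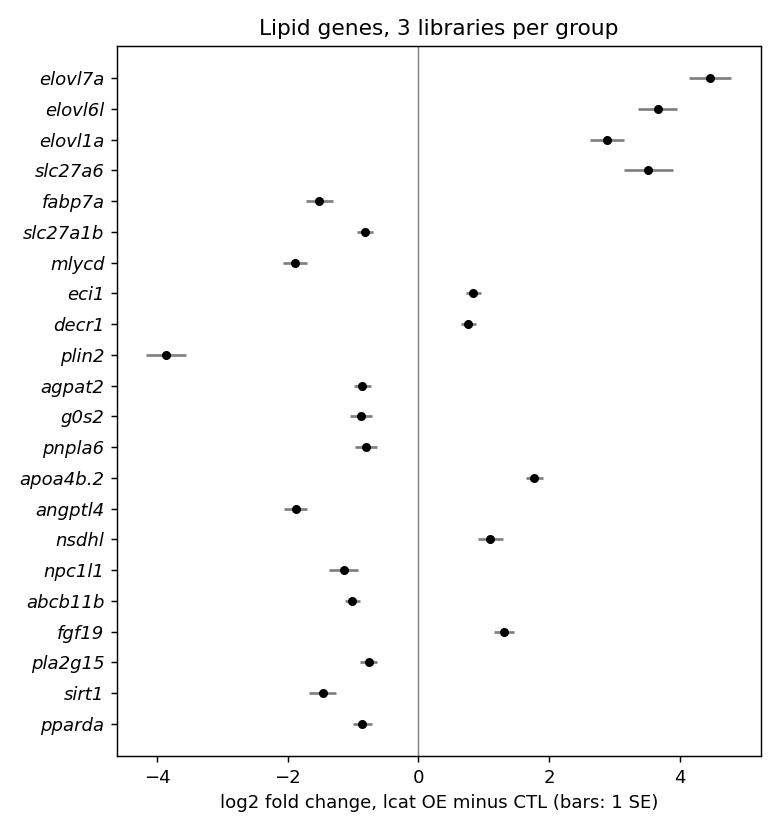
Log2 fold changes (lcat OE minus CTL, n = 3 libraries each) of 22 lipid genes, with bars of 1 SE. The elongase genes lie between 2.89 and 4.47, and plin2 lies at -3.86.

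Lipoprotein, sterol and bile acid genes showed changes in single members. The apolipoprotein list had 7 of 35 genes higher and 7 lower, with equal counts adjusted over the list alone (adjusted p = 0.672), and its median (-0.11) and mean (0.06) differed in sign. Its share of counts was 20.7% in CTL and 25.7% in lcat OE. The gene apoa4b.2 rose from 19.98 to 68.4 CPM (log2 fold change 1.78, SE 0.13) and apodb from 3.36 to 25.4 CPM (2.91, SE 0.33), whereas angptl4, which encodes an inhibitor of lipoprotein lipase, fell from 454 to 124 CPM (-1.88, SE 0.18). Of 27 genes on the cholesterol synthesis list 1 rose and 3 fell (1 and 1 adjusted over the list alone), while 77.8% had a log2 fold change above 0. The list median was 0.67, with an adjusted p = 0.157. The cholesterol synthesis list passed without lcat OE 3 (adjusted p = 0.015, median 0.92) and with 2 against 2 libraries (0.00511, median 1.31). Both settings leave out lcat OE 3. The list was not called with 16 of 19 alternatives (0.00511 to 0.522), and over the 19 its median lay between 0.28 and 1.31. Called members of the list included nsdhl, which was higher (1.1, SE 0.19), and npc1l1, a sterol uptake gene rather than one of synthesis, which was lower (-1.14, SE 0.22). The ggps1 value was -0.57. Its adjusted p of 0.0342 became 0.114 without CTL 2, 0.126 without CTL 3, 0.0883 without lcat OE 1 and 0.113 without lcat OE 2. It passed with 11 of 20 alternatives (0.00418 to 0.134). In the bile acid list 3 of 21 genes rose and 6 fell (4 and 7 adjusted over the list alone; list adjusted p = 0.355). The bile salt export pump gene abcb11b fell from 405 to 201 CPM (-1.01, SE 0.11), fgf19 rose from 20.7 to 51.2 CPM (1.31, SE 0.15), and cyp8b3, with 68 counts in CTL and 2 in lcat OE, had a CTL to lcat OE ratio of 33.0 (95% counting interval 8.80 to 278). The cyp8b3 ratio was 21.7 (5.77 to 183) without lcat OE 1 and 21.4 (5.7 to 180) without lcat OE 2. Without lcat OE 3, which held both counts, cyp8b3 was at least 7.64-fold lower.

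Regulators of lipid genes were lower as a list. In it 3 of 36 genes rose and 10 fell (3 and 12 adjusted over the list alone), with a median log2 fold change of -0.33 (adjusted p = 0.0218; adjusted p = 0.585 with an estimated correlation). The gene listed as LOC100535945, whose RefSeq entry carries the name mlxipl, a carbohydrate-responsive transcription factor, fell from 19.5 to 4.76 CPM (-2.03, SE 0.17), the deacetylase gene sirt1 had a log2 fold change of -1.47 (SE 0.20) and pparda one of -0.86 (SE 0.15). The list's adjusted p was 0.103 without CTL 1, 0.0697 without CTL 3, 0.0962 without lcat OE 2 and 0.0723 with no filter on low counts, within 0.0042 to 0.103 over 19 alternatives. Its median was -0.54 on log2(TPM + 0.1) and -0.21 with length offsets. The regulator list held 0.165% of counts in CTL and 0.117% in lcat OE. Exocrine pancreas markers, lower in the same libraries, went from 0.138% to 0.0218% of counts, and a link to the regulators was not tested. Of 19 genes of fatty acid uptake and activation 4 rose and 4 fell, with equal counts adjusted over the list alone (list adjusted p = 0.672). Among them were the transporter genes slc27a6 (0.480 to 5.54 CPM, 3.51, SE 0.37) and slc27a1b (-0.82, SE 0.13) and the binding protein gene fabp7a (-1.52, SE 0.21). Of 28 phospholipid genes 4 rose and 8 fell, with equal counts adjusted over the list alone (list adjusted p = 0.533). Among them were pla2g12a (1.11, SE 0.12), lpcat4 (1.46 to 5.92 CPM, 2.01, SE 0.32) and pla2g15 (-0.76, SE 0.13).

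Nuclear genes of oxidative phosphorylation were higher. Of 81 tested, 62 rose and 0 fell (68 and 0 adjusted over the list alone), with a median log2 fold change of 0.46 (adjusted p = 6.5e-14; adjusted p = 0.585 with an estimated correlation). Their share of all counts was 1.89% in CTL and 2.44% in lcat OE. The subunit gene ndufa4 rose from 2.97 to 19.4 CPM (2.70, SE 0.24), and ndufc1, matched through its RefSeq name, from 32.9 to 66.5 CPM (1.02, SE 0.11). Over 5 groups of 1696 genes with a mean of at least 1 TPM, ordered by implied transcript length, the median log2 fold change was 0.25 in the shortest and -0.17 in the longest group. With offsets for this trend, an alternative chosen after seeing the data, the list median was 0.20 (adjusted p = 7.37e-05, the highest of 19 alternatives, the lowest being 1.3e-18). On log2(TPM + 1) and log2(TPM + 0.1) it was 0.27 and 0.28. The epidermal markers held 1.26%, 1.61% and 1.05% of counts in lcat OE 1 to 3 and at most 0.0928% in a CTL library.

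Citrate cycle genes had 9 of 26 members higher and 0 lower, with equal counts adjusted over the list alone, and a median of 0.19 (adjusted p = 0.045; adjusted p = 0.585 with an estimated correlation). The share of counts on citrate cycle genes was 0.727% in CTL and 0.714% in lcat OE, while that of the epidermal markers went from 0.0635% to 1.31%. A link between these lists was not tested. The member sdhdb rose from 71.5 to 121 CPM (0.76, SE 0.11). The call of this list was lost with 10 of the 19 other scalings, filters, units and left-out libraries, among them without CTL 2 (adjusted p = 0.151), without CTL 3 (0.0671) and without lcat OE 1 (0.0559), with a range of 0.0294 to 0.237. The citrate cycle median was 0.10 with library totals, 0.09 on log2(FPKM + 1), 0.01 on log2(TPM + 1) and 0.02 on log2(TPM + 0.1). Of 16 genes of NADPH supply 3 rose and 0 fell, with equal counts adjusted over the list alone. The list's adjusted p was 0.103 by camera and 0.00887 by fry. The malic enzyme gene me1 was at 1.08 (SE 0.12) and tkta at 4.24 (SE 0.34), with tkta at only 0.234 CPM in CTL and 4.53 CPM in lcat OE. Of 37 glycolysis and gluconeogenesis genes 3 rose and 6 fell (3 and 5 adjusted over the list alone; list adjusted p = 0.283, but 0.0456 on log2(TPM + 1), within 0.0456 to 0.718), among the higher ones hk2 (1.37, SE 0.23) and pcxa (0.58, SE 0.11).

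Immediate early genes and genes of inflammation were lower as lists. In the list of immediate early and dissociation genes 5 of 40 rose and 21 fell (5 and 23 adjusted over the list alone), with a median log2 fold change of -0.51 (adjusted p = 0.00623; adjusted p = 0.585 with an estimated correlation), among them egr1 (550.03 to 255 CPM, -1.11, SE 0.12) and mych (119 to 40.5 CPM, -1.56, SE 0.12). The list's share of counts was 3.07% in CTL and 3.78% in lcat OE. Its abundant heat shock genes hsp70l (log2 fold change 0.75, adjusted p = 0.351) and hsp70.1 (0.46, adjusted p = 0.415), named after their values were seen, did not pass, and CTL 1 had 3089.5 CPM of hsp70l where CTL 2 and CTL 3 had 10059 and 12375 CPM. In the list of acute phase, complement and inflammation 2 of 46 genes rose and 16 fell (3 and 18 adjusted over the list alone), with a median of -0.23 (adjusted p = 0.0332; adjusted p = 0.687 with an estimated correlation), and the call was lost without CTL 1 (adjusted p = 0.0948), without lcat OE 1 (0.214) and with 4 other settings, with a range of 0.00529 to 0.214 over 19 alternatives. The fry test missed it (adjusted p = 0.0591). This median was -0.05 with length offsets, -0.15 with no filter on low counts, -0.41 on log2(TPM + 1) and -0.42 on log2(TPM + 0.1). The acute phase list held 3.94% of counts in CTL and 3.81% in lcat OE. The share of exocrine pancreas markers fell in the same libraries from 0.138% to 0.0218% of counts, and a link to the acute phase list was not tested. The chemokine gene cxcl18b fell from 57.4 to 5.40 CPM (-3.41, SE 0.29) and stat3 from 25.7 to 10.6 CPM (-1.28, SE 0.15). Of 26 genes of cell death and p53 targets 2 rose and 5 fell, with equal counts adjusted over the list alone (list adjusted p = 0.0504), with gadd45bb at -2.83 (SE 0.25) and gadd45ba at -1.31 (SE 0.13). The cell death list passed by fry (adjusted p = 0.0282), without CTL 1 (0.0453), without lcat OE 3 (0.0491), on log2(TPM + 1) (0.0435) and with length offsets (0.0209), and it was not called with 11 of 19 alternatives (0.0209 to 0.124).

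Cell cycle and DNA replication genes were higher as a list. Of 43 genes 18 rose and 1 fell, with equal counts adjusted over the list alone, and the median was 0.65 (adjusted p = 0.000429; adjusted p = 0.585 with an estimated correlation). The fry test missed this list (adjusted p = 0.0667). Its median was 0.20 on log2(TPM + 1), 0.26 on log2(FPKM + 1) and 0.39 on log2(TPM + 0.1). These genes were at low levels, with 0.017% of counts in CTL and 0.0248% in lcat OE, where the epidermal markers held 0.0635% and 1.31%: hmgb2a rose from 9.99 to 21.4 CPM (1.1, SE 0.15), and ccne2, a cyclin gene, was the one that fell (-1.63, SE 0.23).

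Other hepatic pathways had members in both directions. In xenobiotic metabolism 5 of 42 genes rose and 15 fell, with equal counts adjusted over the list alone (list adjusted p = 0.257; adjusted p = 0.0413 by fry), among them cyp2k18 (-1.76, SE 0.16) and cyp2aa4 (-2.65, SE 0.28). In the oxidative stress list 9 of 40 rose and 8 fell, with equal counts adjusted over the list alone (list adjusted p = 0.832), with txnrd1 at -1.63 (SE 0.12) and nqo1 at -1.2 (SE 0.12). In the unfolded protein response list 5 of 41 rose and 9 fell (5 and 10 adjusted over the list alone; list adjusted p = 0.385), with atf4b at -1.25 (SE 0.18) and xbp1 at -0.87 (SE 0.14). Of 41 lysosome and autophagy genes 8 rose and 10 fell (9 and 12 adjusted over the list alone; list adjusted p = 0.577), with tfe3a at -1.31 (SE 0.14) and ctsla at -1.13 (SE 0.13). Of 50 amino acid and urea genes 4 rose and 6 fell, with equal counts adjusted over the list alone (list adjusted p = 0.415), with got1 at -1.86 (SE 0.19) and gcshb at 0.69 (SE 0.10). Of 73 cytosolic ribosomal protein genes 0 passed the edgeR test in either direction, also adjusted over the list alone, and 5 had an unadjusted p under 0.05. The ribosomal list had a median of 0.11 (adjusted p = 0.0746), which turned to -0.06 on deposited TPM with either pseudocount (adjusted p = 0.991 and 0.538) and to -0.19 with length offsets (0.000265). The ribosomal list passed as higher without CTL 1 (adjusted p = 0.0196), without lcat OE 1 (0.00192, median 0.20), without lcat OE 2 (0.0179) and with no filter on low counts (0.0333).

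**Figure D4:**
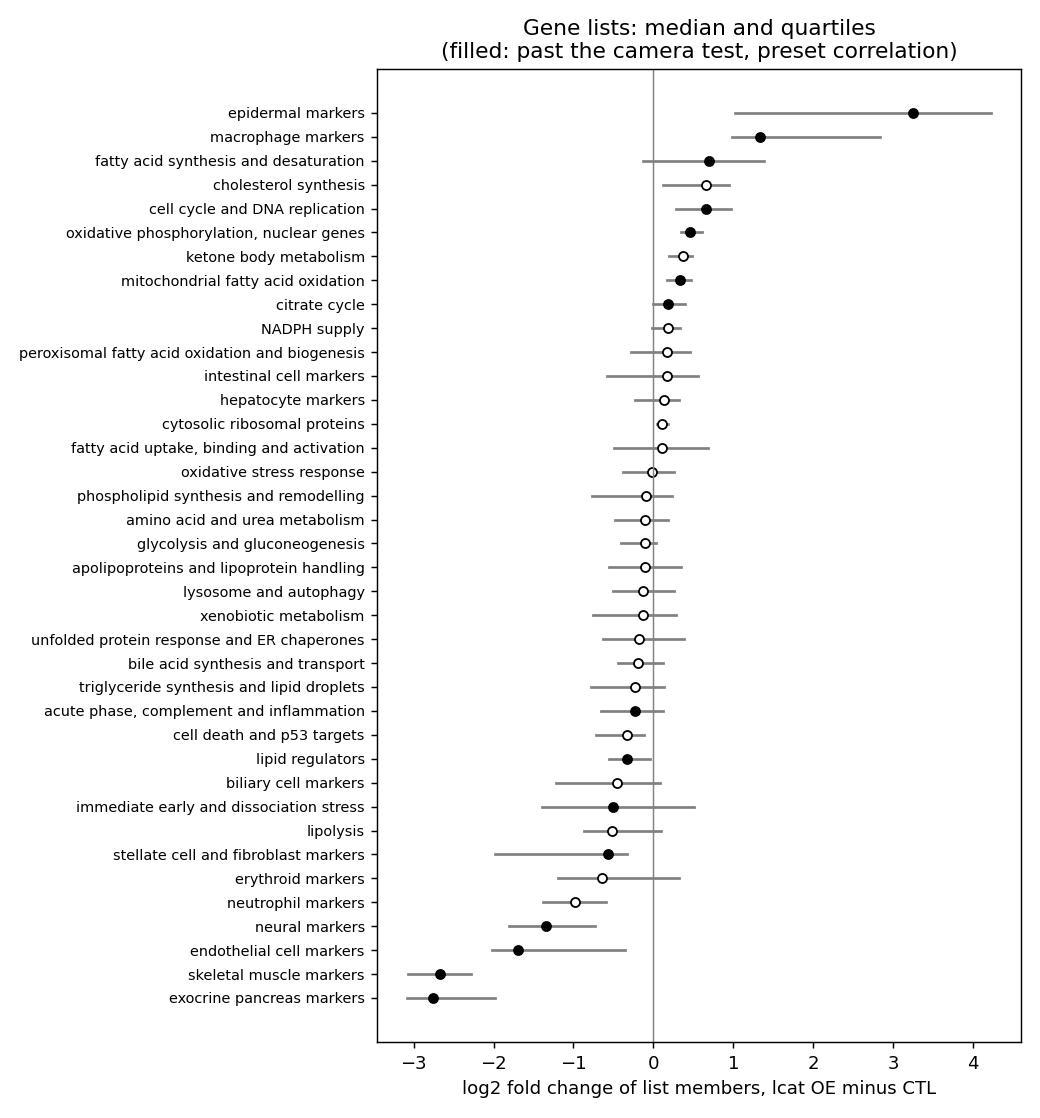
Median (point) and quartiles (line) of the log2 fold changes of the tested members of each of 38 gene lists, lcat OE minus CTL. Filled points mark the 15 lists past the camera test with a preset correlation, from epidermal markers at 3.25 to exocrine pancreas markers at -2.76; with an estimated correlation 0 lists passed.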

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

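The comparison of 2 against 2 libraries and the length offsets were chosen after seeing the data. Of 100 named genes other than lcat and fabp10a, 87 kept their direction and side of the threshold under every alternative that tested them, 13 lost their call under at least 1, and 0 reversed; 17 were not tested with at least 5 CPM in 3 libraries. The lcat log2 fold change was 4.02 to 4.49 over all alternatives. Leaving out 1 library at a time gave 4.07 to 4.44 for lcat, 0.06 to 0.20 for the fabp10a log2 fold change, 1773 to 2441 genes higher, 1740 to 2253 lower, 5 to 8 lists higher and 6 to 10 lower.

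With at least 5 CPM in 3 libraries, which tests fewer genes (6580), 1335 genes were higher, 1369 lower and 5 lists lower. With a 2-fold threshold 1075 were higher and 1264 lower. On log2(TPM + 1) 1318 genes were higher and 3040 lower, and on log2(TPM + 0.1) 1356 were higher and 3050 lower. The fabp10a log2 fold change was -0.0253 on both, and the cause of these shifts was not tested. With length offsets it was -0.21, and the median of cytosolic ribosomal proteins (list median log2 fold change) reversed to -0.19, by removal of a trend on length. An estimated correlation left 0 lists higher and 0 lower by camera, 2 having an unadjusted p under 0.05, while fry called 17. DESeq2 called 2245 genes higher and 2202 lower, 3971 of them shared with the main calls, and 2 against 2 libraries called 2180 and 2127.

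Replicate numbers did not pair the samples: deviations of same-numbered libraries correlated at -0.0466, -0.0294 and 0.0163, and 1 of 6 samples correlated best with its own number. With the replicate block 2040 genes were higher and 2152 lower, the cholesterol synthesis list passed (adjusted p = 0.0189; 0.00511 to 0.522 over 19 alternatives), and the calls of the acute phase list (0.051), the citrate cycle list (0.0586) and oxct1b (0.0761) were lost. A correction from given transcript lengths was not run. Depth limits genes with few counts in 1 group, such as aox5, whose bound rests on the floor of 3 counts.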

Other observations

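The splits of the samples, the tests on marker genes, scaling and epidermal rank, and the lists of superficial epidermis, basal epidermis, xanthophores and photoreceptors were chosen after the results were seen. Of 14 photoreceptor genes 13 fell and 0 rose, with a median log2 fold change of -3.23, but the values of 7 had been seen when the list was drawn up. Of the 7 others 6 fell, with a median of -2.98, and 95% of 10000 random lists matched on level had medians between -1.05 and 0.73. These lists were drawn gene by gene, whereas photoreceptor genes can move together, so that range may be too narrow. The 7 others are therefore not separate evidence from the 7 seen before. Of 14 xanthophore genes, a yellow pigment cell type, 12 fell and 0 rose, with a median of -6.24, also with the 2 genes without a count in lcat OE at their bounds; 12 of the 14 had been picked after their values were seen. The gene zgc:171534, chosen after its values were seen, had 126, 103 and 124 CPM in the CTL libraries and 0.08, 0 and 0 CPM in lcat OE.

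In the other splits of the 6 libraries into 3 against 3, of which there are 10 with the real one, edgeR called at most 0 genes against 4596 in the real split, and the unadjusted p was under 0.05 for 103 to 348 genes against 6053. Only 1 of 10 splits gave as many genes, and with 10 splits the share cannot go under 0.1. Each of the other splits mixes CTL and lcat OE libraries on both sides. The difference between the groups then adds to the spread within each side, which by itself lowers the number of genes called. The gene counts of these splits therefore do not show how many calls chance alone would give. For lists tested by camera with the preset correlation, 3 of 10 splits, the real one included, gave at least the 15 real calls, and the highest other split gave 16.

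Markers of other cell types moved apart between the groups. A lower share of hepatocytes in 1 group, with the same mix of other cells, would raise all of these markers alike. The exocrine pancreas list (median -2.76) and the epidermal list (3.25) moved in opposite directions. This does not exclude a lower share together with a different mix of other cells. Cells of the superficial epidermis in the lcat OE sorts are a candidate source: superficial genes whose values had not been seen had a median of 1.56 (16 genes, 8 higher and 3 lower), and krt4, named after its values were seen, reached 3493 CPM, although 3 of all 25 fell against 17 that rose (cdh1 -0.511, tjp3 -0.716 and sdr16c5b -0.343), all 20 fixed epidermal markers were at 1 CPM or more in CTL and 2 are in another list. Whether the basal layer came with them cannot be told apart: of 10 basal genes 0 rose and 2 fell (median -0.179, below the lower quartile of all superficial genes, 0.217, but not of those not seen before, -0.33), and krtt1c19e (4.99) and krt5 (3.84), known from basal cells too and added after their values were seen, rose, with an upper quartile of 0.569 over the 12 genes and of 3.09 over the 6 at 2 CPM or more in either group, against a superficial median of 1.98. Xanthophores in the CTL sorts stay open too, since their genes, at 2.78 times the level of CTL 1 and CTL 3 in CTL 2 (0.906 to 1.06 in 10000 random lists), were picked for this pattern, and exocrine pancreas (2.02) and epidermal (1.97) markers had a like excess in CTL 2, against 0.916 for hepatocyte markers. A sort on the fabp10a reporter should remove such cells, the gates are not given in the sources used here, and expression of these genes in hepatocytes under lcat was not tested.

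The rise of oxidative phosphorylation genes was weighed against 3 explanations. Short transcripts may account for part of it. Random lists matched on level and implied length had a median of 0.203, with 95% between 0.115 and 0.307. The oxidative phosphorylation list stood above them at 0.463. The random lists were drawn gene by gene, whereas genes of this list can move together (estimated correlation 0.161), so that range may be too narrow. With lengths that are only implied, these lists do not settle whether length alone could give the whole rise. Other scalings and units did not remove it, the lowest median over library totals, TPM and FPKM being 0.274. RNA of epidermal cells cannot be told apart from a change in hepatocytes, since both measures separate the groups and 3 lcat OE libraries are too few to decide: 1 had the same rank in both mean log2 levels, the middle one of a reversed order, and lcat OE 3 had the highest share of oxidative phosphorylation counts (2.47%) and the lowest epidermal share (1.05%). An effect of lcat stays open and was not tested separately.

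Of the genes past the threshold with no overlap, 49 had a mean under 1 CPM in 1 group and at least 10 CPM in the other, 35 of them on in lcat OE and 14 in CTL. Inherited sequence differences between the 2 fish lines could give such genes in linked blocks, but 2 of the 47 genes with a known neighbour order had another within 10 genes, where 10000 random sets gave 0 to 8. With the cutoff first planned, a log2 fold change of at least 4 in place of no overlap, it was also 2, of 42 genes. This result met the outcome written beforehand as speaking against the explanation, but that outcome was set wrongly, since unlinked differences need no neighbours. Line differences and the group therefore cannot be told apart, and no biological explanation was tested.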
